A study of Mus musculus with 10 samples.

How the data were processed

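RNA from 10 mouse samples was measured on 1-colour microarrays, 1 array per sample. Per the labels, amplified RNA was coupled to a Cy5 dye and hybridised to Toray mouse chips. The samples were mouse embryonic fibroblasts (MEF), heart tissue, and 8 samples of induced cardiomyocyte-like cells (iCM), sorted for GFP driven by the cardiac α-MHC promoter. Per the labels, the iCM came from MEF given the GMT factors by retrovirus, with or without a synthetic mimic of the microRNA miR-133a.

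The deposited scanner files give, per the file headers, the median intensity of each of 27456 spots and the median intensity around it, with no normalization. Of these spots, 23474 carry probes, which make 23473 probes because 1 is spotted more than once and was averaged, and 2736 are blank. A value table from the authors holds intensities for the same 10 arrays on a linear scale. Each of its columns is a straight line of the spot intensities of 1 scanner file, has a median of about 25.0, and leaves dim probes empty. How the authors chose the probes to leave empty is not given in the sources used here. The columns for days 3 and 7 match the scanner files deposited for the other day, with the arm kept. The scanner files were used as assigned to their samples, and the exchanged days were run as an alternative.

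Spot intensities were corrected with the normexp model fitted to the blank spots of each array (limma 3.58.1 under R 4.3.3, offset 50), quantile-normalized over the 10 arrays and log2-transformed. This departs from the design written before the data were examined, which took normexp on the local background column. That column followed the light of the spot itself: its Spearman correlation with spot intensity was 0.828 to 0.954 across probes and 0.161 to 0.268 across blank spots. The standard deviation of the day 18 pair's differences was 0.46 (log2) with the local background, 0.17 with the blank spots and 0.22 with no subtraction. These 3 backgrounds were tried on the data and the change was made with their results in view. The values of the main counts, set shifts and rank correlations under the designed background are therefore printed with the results or in the account of the alternatives.

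A probe was called detected on an array when its spot exceeded the 95th percentile of that array's blank spots. Detected probes made up 77.8% to 87.7% of the chip. This cutoff is lenient, since spots named as having no probe came near it. Their median was 17 against a cutoff of 16 on the day 3 GMT array, and 25 against 27 on the day 7 GMT array. Detected therefore need not mean a signal above such spots. Differences between iCM arms and between days were tested over the 19932 probes detected on at least 3 of 6 iCM arrays. The test was limma's moderated linear model with arm and day as terms, 2 residual degrees of freedom before moderation, and Benjamini-Hochberg adjustment at 0.05. Each arm has 1 array per day, so the 3 days stand in for replicates, and the p-values measure only the spread of the arm difference between days. In the day test both arms of a day stand in for replicates instead. Comparisons with 1 array on a side have no replicate check and no p-value. On data simulated for the 3 pairs over 19932 probes, the test recovered 21 of 50 probes changed 1.5-fold, 41 of 50 changed 2-fold, 44 of 50 changed 3-fold and 48 of 50 changed 4-fold. It called 5 unchanged probes. The simulated change was equal at all 3 days and fell on probes drawn at random, so these recoveries need not hold for the real arrays. On the real arrays, 18 probes differed at least 2-fold in the mean with the same sign at all days, and 0 probes were called.

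The file headers place the arrays in 3 scan sessions. The first held MEF, heart, and the pairs of days 3 and 18, the second held the day 7 pair, and the third held a second day 7 GMT/miR-133 array and the Snai1 array. Day as a term also takes up the session, so the arm difference lies within sessions, while day 7 and its session cannot be told apart. The second day 7 GMT/miR-133 array carries miR-133 in its title and treatment but GMT alone in its description. It was kept out of the main tests and used as the control of the Snai1 array.

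The files used here do not pair probe IDs with genes. None of the 325 genes in the 19 gene and marker lists fixed in advance could be matched to a probe, and 0 probe IDs were found in the reference gene table, so no gene is named. In place of the lists, 2 probe sets were taken from the control arrays after the data had been seen: heart-high probes, at least 4-fold higher in heart than in MEF, and MEF-high probes, at least 4-fold lower. Their tests had been seen in a first look as well. The sets use no iCM array. Set tests were made with limma's camera, with a preset correlation of 0.01 and with an estimated one, and with fry, adjusted over 2 sets and both comparisons. For single arrays, a set's median was placed among 10000 random probe sets matched on mean level. The naming rule took the largest changes among probes past the test, then those with the same sign at all days ordered by their smallest difference, or the largest differences for single arrays. Only the first 2 in each direction per comparison are printed. A probe is its own unit here, so keeping all probes apart changes nothing.

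Alternatives covered the background, the offset, scaling to the median, cyclic loess, the authors' value table, the dim filter, left-out days, the second day 7 array, the variance model, the day term and the fold thresholds. Set membership stayed fixed across them except where the set threshold itself was changed or where the dim filter dropped members, as with probes detected on all arrays. Sites matching the miR-133 seed were not analysed here because the test needs annotated transcript sequences.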

Results

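Gene expression was profiled in MEF, in mouse heart and in iCM, which are fibroblasts driven toward a cardiac-like state by the transcription factors Gata4, Mef2c and Tbx5 (GMT). The series set MEF as the negative control and heart as the positive control, with 1 array each. The iCM were sorted at days 3, 7 and 18 after GMT alone or after GMT with miR-133, a microRNA abundant in muscle, with 1 array per arm and day. A later round added a second day 7 GMT/miR-133 array and 1 day 7 array of GMT, miR-133 and Snai1, a transcription factor that drives epithelial-mesenchymal transition. Between 18259 and 20583 of 23473 probes were detected per array, fewest on the 2 arrays of the later round, and the number of arrays limits the precision of every value. The files do not pair probes with gene names, so probe groups defined by the controls carry the description and single probes are given by ID. No value measured on 1 array per side has a replicate check.

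Heart and MEF, the end points of the conversion, differed at least 4-fold at 800 probes, 3.41% of the chip. Of these, 462 were higher in heart (heart-high) and 338 were higher in MEF (MEF-high). Scaling each array to its median turned this split to 293 higher in heart and 467 higher in MEF, and the background as first designed gave 372 and 270. Most of them exceeded the detection cutoff on both arrays: 40 heart-high probes were not detected in MEF and 7 MEF-high probes were not detected in heart. Spots without a probe had a median at that cutoff on both arrays, 17 in MEF and 16 in heart. Among the largest differences toward heart were M200000622, 9.59 on the log2 scale, and M400010807, at least 9.53, a lower bound because its spot was saturated in heart. The largest toward MEF were at M200007659, −6.47, and M200009370, −6.44. M200000622 in MEF and M200007659 in heart were both at 5.75, near the low end of the scale, so these sizes depend on the processing. They were 8.90 and −5.03 with the background as first designed, and 13.78 and −10.09 in the authors' value table. Heart tissue holds several cell types, so a heart-high probe is not by itself a cardiomyocyte probe.

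The comparison of iCM with MEF asked how far the sorted cells had left the fibroblast profile. Across the 6 iCM arrays of the first round, 265 probes were at least 2-fold higher than in MEF on every array and 484 were at least 2-fold lower on every array. The lower group held 190 MEF-high probes, 56.2% of that set, against 6.97 for independent lists. The higher group held 83 heart-high probes, 18.0% of that set, against 5.22. Simulated unchanged arrays sharing the MEF array gave overlaps of 0.05 and 0 on average over 100 draws, a value that leaves out real effects. Part of the excess may still come from the shared MEF array.

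MEF-high probes thus moved further toward heart than heart-high probes did. Probes carry no gene names here, so which cell types or processes the sets reflect is not known. The median of MEF-high probes relative to MEF was −1.82 ± 0.16 (log2, SD, n = 6 arrays), compared with −2.63 in heart. The median of heart-high probes was 0.46 ± 0.10 (log2, SD, n = 6 arrays), compared with 2.85 in heart. Of the heart-high probes, 252 (54.5%) stayed within 2-fold of MEF on all 6 arrays, and 22 came within 2-fold of heart on all 6. Of the MEF-high probes, 105 (31.1%) came within 2-fold of heart on all 6. The largest iCM differences from MEF were at M400000392, 8.74 ± 0.24 (log2, SD over 6 arrays), and M200000014, 8.46 ± 0.34, both also heart-high. M200000014 was at 14.05 to 14.84 on these arrays, above the 13.16 of heart. Whether either probe measures a factor given by retrovirus cannot be told without gene names. In the other direction they were at M200001169, −6.62 ± 0.95, and M200006465, −5.99 ± 0.39, both MEF-high. With the background correction as first designed, 193 probes were higher and 301 lower. On the 4 iCM arrays scanned in the session of MEF and heart, 395 were higher and 574 lower. A rule that must hold on fewer arrays can only give more probes, so this rise does not by itself reflect the session. Without day 3 the counts were 281 and 497, and without day 18 they were 305 and 564.

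**Figure D1:**
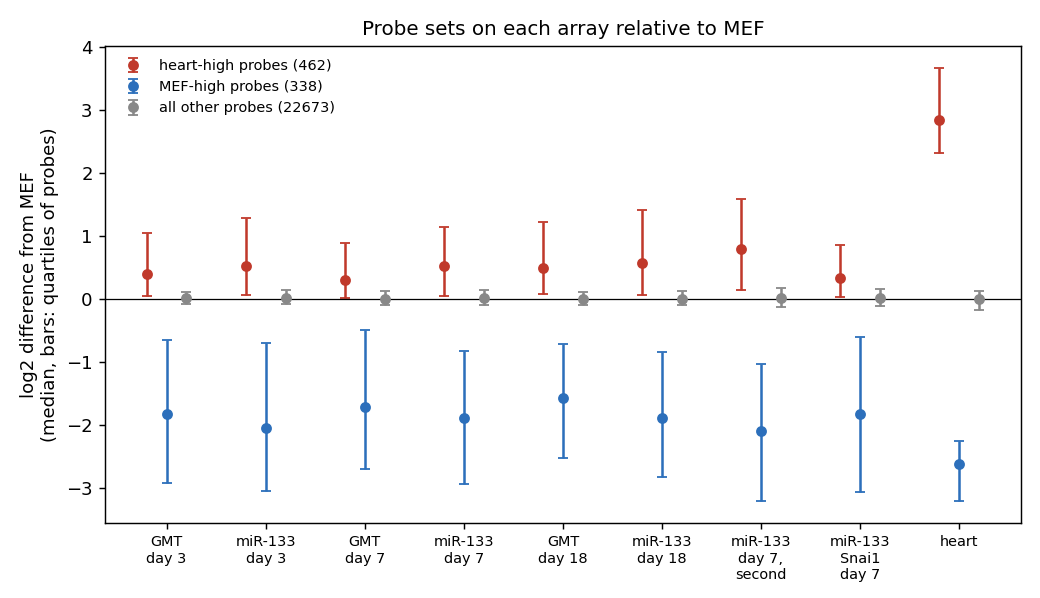
Medians of the heart-high, MEF-high and all other probes on each array minus MEF (vertical axis, log2; bars span the quartiles of the probes; horizontal axis, arrays). The MEF-high medians of the iCM arrays, −1.57 to −2.09, lie between MEF and the −2.63 of heart, while their heart-high medians, 0.30 to 0.79, lie far below the 2.85 of heart.

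The 2 arrays of the later round, which took no part in choosing these probes but were set against the same MEF array, agreed on most of them. Of the 265 higher probes, 253 were at least 2-fold above MEF on the second day 7 GMT/miR-133 array and 210 on the Snai1 array. Of the 484 lower probes, 476 and 440 were at least 2-fold below MEF on these arrays. Sizes did differ: M400000392 was at 14.46 to 14.94 (log2) on the 6 first-round arrays and at 11.32 and 10.85 on the second day 7 array and the Snai1 array.

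The comparison of GMT/miR-133 with GMT asked what the microRNA adds. Heart-high probes were higher with miR-133 at each day, by a median of 0.086 at day 3, 0.11 at day 7 and 0.087 at day 18 on the log2 scale, a mean of 0.095 ± 0.016 (SD, n = 3 days). MEF-high probes were lower at each day, with medians of −0.061, −0.14 and −0.17 and a mean of −0.12 ± 0.057 (SD, n = 3 days). Of 443 tested heart-high probes, 41.5% were higher with miR-133 at all 3 days, compared with 14.4% of the 19160 tested probes in neither set. Of 329 tested MEF-high probes, 41.3% were lower at all 3 days, compared with 14.4% of probes in neither set. By limma's camera with a preset correlation, both sets passed, with an adjusted p of 2.74e-15 for heart-high and 4.71e-19 for MEF-high probes. With an estimated correlation, heart-high probes passed at an adjusted p of 0.0322 and MEF-high probes did not, at an adjusted p of 0.0689. By fry, the adjusted p was 0.0207 for heart-high and 0.0485 for MEF-high probes. With the first-round arrays these shifts were at most 1.13-fold in the median at any day, and both sets were chosen after the data had been seen. With the background as first designed the mean shifts were 0.049 for heart-high and −0.095 for MEF-high probes. They were 0.168 and −0.165 with the second day 7 array in place of the first, and 0.142 and −0.293 in the authors' value table.

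No single probe passed the test between the arms. Of 19932 probes, limma called 0 at an adjusted p of 0.05, with a smallest adjusted p of 0.202, and 1919 had an unadjusted p under 0.05, compared with 996.6 expected by chance. That count depended on the processing: 79 probes were called without background subtraction, 102 with an offset of 16, and 161 with a trended and robust variance model. By size alone, 18 probes differed in the same direction at all 3 days with a mean of at least 2-fold, 5 higher and 13 lower, while the 3 other sign patterns of the pairs gave 0, 1 and 0. The 5 higher probes included 3 heart-high ones, and the 13 lower probes included 7 MEF-high ones. With the background as first designed, 94 probes met this rule, 69 higher and 25 lower, so the balance turned, and the other sign patterns then gave 23 to 129. With the second day 7 array in place of the first, 35 were higher and 37 lower.

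Among probes higher with miR-133, M300012836 differed by 1.29, 1.45 and 0.79 on the log2 scale at days 3, 7 and 18 (limma, adjusted p = 0.213). M300001423 differed by 1.02 in the mean and by at least 0.74 at each day (limma, adjusted p = 0.278). Both are heart-high. Among probes lower with miR-133, M200013648, a MEF-high probe, differed by −1.42, −1.74 and −1.33 (limma, adjusted p = 0.202). M300002557, which is in neither set, differed by −1.49, −1.20 and −2.61 (limma, adjusted p = 0.278). These 4 did not pass the test. The 2 day 7 arrays labelled GMT/miR-133 differed at them by 2.99, 2.53, −2.66 and −0.36 (second minus first, log2), which at the first 3 is more than the difference between the arms at any day.

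**Figure D2:**
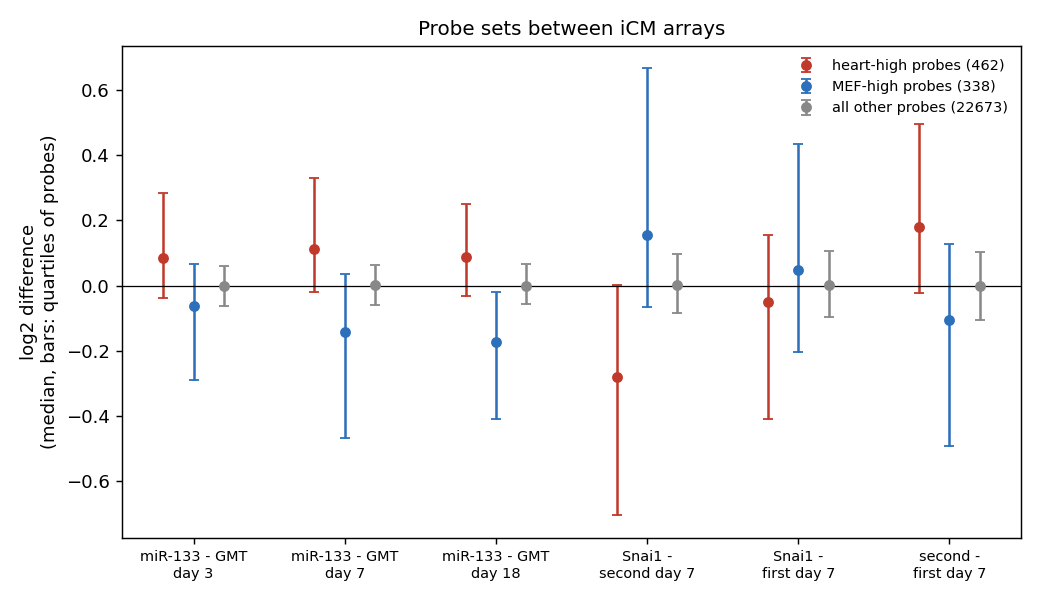
Medians of the 3 probe groups in differences between iCM arrays (vertical axis, log2; bars span the quartiles of the probes; horizontal axis, the pairs of arrays). Heart-high medians are above 0 and MEF-high medians below 0 for miR-133 at each day. The heart-high median of the Snai1 array is −0.28 against the second day 7 array and −0.051 against the first.

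The comparison of day 18 with day 3 asked what differed between these days. Both arms of a day stand in for its replicates, so the p-values measure only how far the arms disagree across days. Time in culture therefore cannot be told apart from a difference in preparation or sort. With limma, 98 probes passed the test, 74 rising and 24 falling, and 3504 had an unadjusted p under 0.05. The 74 rising probes included 19 MEF-high ones, compared with 1.22 for independent lists, and 6 heart-high ones, compared with 1.64. The 24 falling probes included 5 MEF-high ones, compared with 0.396, so MEF-high probes were in excess in both directions. The largest rises were at the MEF-high probes M400005459, 5.72 ± 0.18 (log2, SE; limma, adjusted p = 0.0137), and M400000367, 4.63 ± 0.094 (limma, adjusted p = 0.00387). The largest falls were at M200013648, also MEF-high, −1.56 ± 0.11 (limma, adjusted p = 0.0337), and M200008489, −1.45 ± 0.13 (limma, adjusted p = 0.0446). With days 3 and 7 exchanged the rises were 5.82 and 4.69 and the falls −3.49 and −0.42. In the authors' value table the rises were 8.41 and 7.42 and the falls −3.90 and −0.63. With the background as first designed the rises were 4.08 and 4.10 and the falls −1.19 and −1.35. As a set, MEF-high probes were 0.16 higher at day 18 with GMT and 0.088 higher with GMT/miR-133 in the median (log2). Heart-high probes were 0.057 and 0.045 higher. The mean over both arms was 0.124 for MEF-high and 0.051 for heart-high probes. It was 0.0103 for MEF-high probes in the authors' value table, and 0.0061 for heart-high probes with the background as first designed, where their preset call was lost (unadjusted p = 0.215). The preset camera test called both sets, with an adjusted p of 1.35e-05 for MEF-high and 0.000116 for heart-high probes. Neither passed with an estimated correlation, at an adjusted p of 0.176 for MEF-high and 0.0666 for heart-high probes. By fry, the adjusted p was 0.0580 for MEF-high and 0.0436 for heart-high probes.

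The count of day calls is not firm. It was 0 with the background as first designed, 39 without the day 7 pair, 13 (12 rising) with median scaling, 596 without background subtraction and 3317 when days 3 and 7 were exchanged as the authors' value table has them, 1687 rising and 1630 falling. Which deposit carries the right days cannot be told from the files, so each value printed for day 3 or day 7 holds for the scanner files as assigned.

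The Snai1 array was compared with the second day 7 GMT/miR-133 array, scanned in the same session, to see what adding Snai1, a reported miR-133 target, does to the miR-133 profile. Heart-high probes were lower with Snai1, by a median of −0.28 on the log2 scale, and MEF-high probes were higher, by 0.16. These medians were at percentiles 0 and 100 of random matched sets, but the difference of the 2 same-label day 7 arrays was at percentiles 100 and 0 as well, so the percentiles do not set Snai1 apart. At least 2-fold, 159 probes were higher and 233 lower, and the lower group held 70 heart-high probes, compared with 4.59 for independent lists, and the higher group 45 MEF-high probes, compared with 2.29. With median scaling, 220 probes were higher and 193 lower, and with the background as first designed 333 and 315. The heart-high and MEF-high medians were −0.13 and 0.094 with the background as first designed, and −0.71 and 0.066 in the authors' value table. The largest differences were at M300004979, 2.78, and M300003525, 2.78, in one direction, and at M200002898, −3.64, and M300020782, −3.46, in the other. All 18 probes that differed in the same direction with miR-133 at 3 days differed the opposite way with Snai1 against this control, and 10 of them did against the first day 7 array.

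The control array decided much of this. The 2 day 7 arrays labelled GMT/miR-133 differed from each other at least 2-fold at 363 probes, 190 higher on the second and 173 lower, with 47 heart-high probes among the higher and 31 MEF-high probes among the lower. Median scaling turned this split to 134 higher and 295 lower, and without background subtraction it was 303 and 317. By the days of the authors' value table, the first array would be a day 3 array, and these 2 arrays would then differ in day as well. No alternative with exchanged days was run for them. Against the first day 7 array, from another session, the heart-high median of the Snai1 array was −0.051 and the MEF-high median 0.049, and M300004979 turned to −0.35, while M300003525 was at 1.67, M200002898 at −2.02 and M300020782 at −2.88. Among 13 probes that differed 2-fold with miR-133 in 1 direction at days 3 and 18 as assigned, 12 went the opposite way with Snai1 against the second array. Against the first, 6 did. Neither of these 2 control arrays took part in choosing the 13 probes. Against both control arrays, 60 probes were at least 2-fold higher with Snai1 and 83 lower, with 17 MEF-high probes among the higher and 21 heart-high probes among the lower. The labels of the second array conflict, because its description names GMT alone. GMT alone would give its difference from the first array the sign opposite to miR-133, and a like array would give no set sign. The difference had the miR-133 sign at 10 of the same 13 probes, and its r with the miR-133 difference of days 3 and 18 was 0.291 across probes, which are not independent replicates.

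By rank correlation over the whole profile, miR-133 did not bring the cells measurably closer to heart. Spearman's rho with heart across 22236 probes was 0.889 to 0.897 on the 6 iCM arrays, and 0.880 for MEF. The change of rho with heart from GMT to GMT/miR-133 was 0.000641 ± 0.00465 (SD, n = 3 days), smaller than its spread, while rho with MEF changed by −0.00995 ± 0.00337 (SD, n = 3 days) and was lower with miR-133 at all 3 days. With the background as first designed these changes were −0.0151 with heart and −0.0215 with MEF. Pearson's r of the linear scanner intensities with the heart column of the authors' value table was higher with miR-133 at each day. With GMT and GMT/miR-133 it was 0.619 and 0.628 at day 3, 0.607 and 0.630 at day 7, 0.618 and 0.639 at day 18. These correlations are across probes, which are not replicates.

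**Figure D3:**
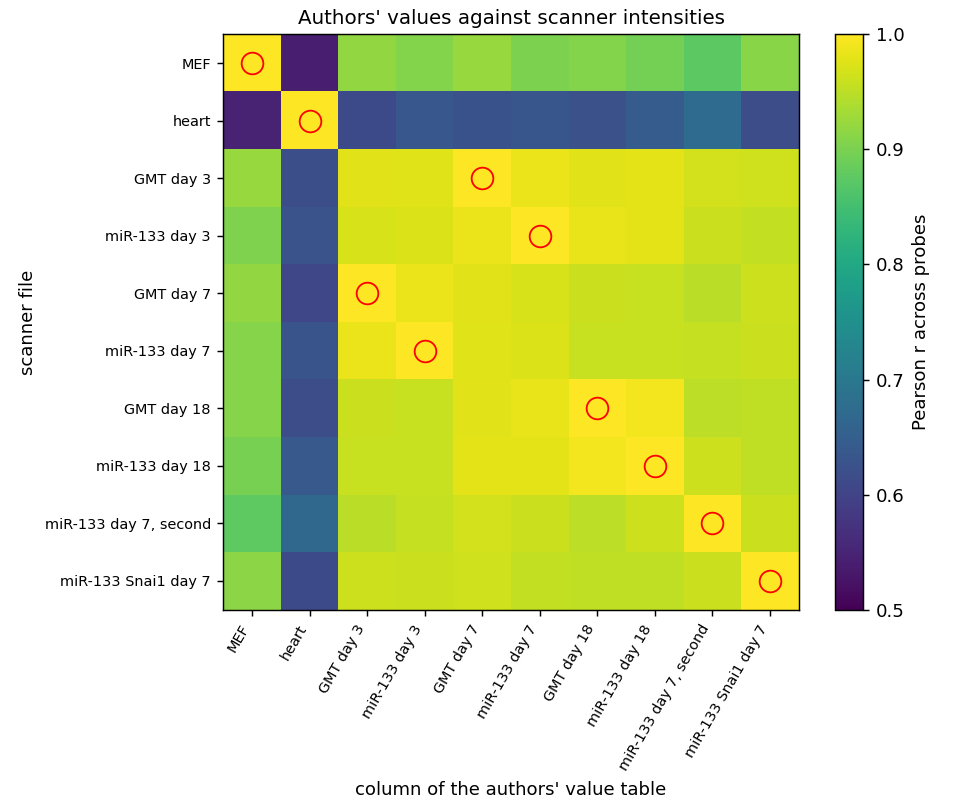
Pearson's r across probes between each column of the authors' value table (horizontal axis) and each scanner file (vertical axis); circles mark the best file of each column. The 4 columns of days 3 and 7 match the file of the other day in the same arm, and the other 6 columns match their own file.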

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

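All tests in this part were chosen after the result was seen. No group had enough arrays for a test of outlying samples, and the probe sets moved the same way under miR-133 at all 3 days, so the 1 result brought up here comes from the authors' value table. In it, 4 columns, those of the first-round iCM at days 3 and 7, matched the scanner file of another sample best. Ordinary likeness of arrays is argued against: these columns match the other day's file at an r that rounds to 0.99999, while the highest r of any column with a file that is not its match was 0.992. Whether the files or the columns carry the wrong day stays open. The file deposited for day 3 had a rank correlation with day 18 higher by 0.0130 than the one deposited for day 7, but the day 7 files were scanned in another session, so time and session cannot be told apart. No biological explanation was tested, and the comparison of arms within days is the same under either reading.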

How the results depend on the processing

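The main background, the probe sets and their thresholds, exchanged days and the first day 7 control were chosen after seeing the data. The local background was the design's own and became an alternative when the main one replaced it; the other settings were fixed before the data were examined. Of 198 alternative values of the main results, 142 stayed within the limits set (counts within 1.5 times, tests on the same side with the same sign, other values within 1 SD), and no called value reversed. Totals hide turned splits, which other settings below gave too: median scaling gave 293 higher and 467 lower for heart against MEF, 220 and 193 for Snai1, and 134 and 295 for the same-label pair. Of 128 alternative values for single probes, 66 stayed within the SD of the same-label pair's differences, 61 moved further with the same sign and 1 reversed. The reversed value was M300004979 at −0.35 with the first day 7 control. The miR-133 set shifts kept their sign and their preset call in all settings run; without 1 day they were 0.086 to 0.10 for heart-high and −0.16 to −0.10 for MEF-high probes, and with the second day 7 array in place of the first 0.168 and −0.165. The cause of the changes below was not tested unless named.

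Without background subtraction, counts were 79 for miR-133, 596 for day, 618 for Snai1 and 620 (303 higher) for the same-label pair. With an offset of 16 they were 102, 654, 718 and 721 (353 higher), with 1275 for heart against MEF. Median scaling gave 13 day calls, 12 of them rising. For the authors' value table, empty probes were filled with the lowest value of their column and no further normalization was made. Probes with a value in it were taken as detected. The authors' value table, which has no offset and other days, gave 4226 day calls (1297 rising), 166 probes in 1 direction with miR-133, 2243 for heart against MEF, 1902 for iCM against MEF, 2611 for Snai1 (627 higher), 2686 for the same-label pair (1149 higher), miR-133 set shifts of 0.142 and −0.293, a day shift of MEF-high probes of 0.0103, and Snai1 set medians of −0.71 and 0.066.

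The designed local background gave 0 day calls, 94 probes in 1 direction with miR-133 (69 higher), 642 for heart against MEF, 494 for iCM against MEF, 648 for Snai1 (333 higher), 1166 for the same-label pair (574 higher), miR-133 set shifts of 0.049 and −0.095, Snai1 set medians of −0.13 and 0.094, a day shift of MEF-high probes of 0.10, a day shift of heart-high probes of 0.0061 that no longer passed, and rho changes of −0.0151 with heart and −0.0215 with MEF. Mean rho with heart was 0.894, and 0.926 with cyclic loess, 0.905 with the value table, 0.817 with the local background, 0.905 without the dim filter and 0.863 over probes detected on all arrays, where the MEF change was −0.0143 and the Snai1 MEF-high median 0.24.

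Day calls numbered 3 without the dim filter, 39 without day 7, 12 with the second day 7 array added, 2 with it in place of the first, 727 with the trended variance model and 3317 with exchanged days (1687 rising); the second day 7 array in place of the first gave 72 probes in 1 direction with miR-133 (35 higher). The trended model called 161 probes for miR-133. Other fold thresholds, by construction, gave 114 (1.5-fold) and 1 (3-fold) for miR-133, 229 for iCM, 2648 for heart against MEF (1268 higher) and 39 for Snai1. With the mean of both day 7 arrays as control the heart-high Snai1 median was −0.14; with the first it was −0.051, and 0.049 for MEF-high probes. The planned limma fit over 8 iCM arrays borrows the spread of the lone Snai1 array from the other arms, so its count of 484 is no test of Snai1.

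The day shift of MEF-high probes lost its call with exchanged days (0.069), with sets at 2-fold (0.018), with an estimated correlation (adjusted p = 0.176) and with fry (adjusted p = 0.0580). With an estimated correlation, the calls of MEF-high probes under miR-133 (adjusted p = 0.0689) and of heart-high probes by day (adjusted p = 0.0666) were lost. Arms were paired by day in the main model; without the day or arm term as a block, 0 probes were called for miR-133 and 68 for day. Seed-site alternatives were not run. Signal over background limits low probes: the median probe was 1.4 to 3.2 times the blank.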

Other observations

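All tests of explanations in this part were chosen after the results were seen. Many probes that set iCM apart from MEF do not set heart apart from MEF. Of the 265 probes higher in all 6 iCM arrays, 124 lay within 2-fold of MEF in heart, and their median over MEF was 1.67 to 1.86 (log2) on these arrays and 0.034 in heart. With miR-133 they were higher by a median of 0.15 at day 3, 0.057 at day 7 and 0.12 at day 18. With Snai1 they were lower, by −0.35 against the second day 7 array and −0.28 against the first, with 97 and 83 of the 124 probes lower. The 83 probes that were also heart-high were 0.31, 0.16 and 0.22 higher with miR-133 at the 3 days. With Snai1 they were lower by −0.87 against the second day 7 array and by −0.27 against the first, while the second day 7 array was 0.58 above the first. Both groups were chosen partly for being high on the first day 7 array, which by itself favours lower Snai1 values against it.

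MEF-high probes lay nearer to MEF at day 18 than at day 3 in the scanner files as assigned. The 190 MEF-high probes that were lower in all 6 iCM arrays were 0.30 higher at day 18 than at day 3 with GMT, in 148 of the probes, and 0.19 higher with GMT/miR-133, in 141 of them (medians, log2). At day 18 they were −2.34 from MEF with GMT and −2.62 with GMT/miR-133. M400005459 was at 12.03 and 11.38 in the 2 arms at day 18 and at 13.79 in MEF, but at 5.72 to 6.13 on the other 6 iCM arrays, and M400000367 had the same form, at 10.72 and 10.35 at day 18 and 5.75 to 6.03 on the other 6. Whether the day 18 cells came from another fibroblast preparation is not stated in the labels, and no explanation was tested.

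The shift of GMT/miR-133 arrays toward heart in both probe sets was weighed against technical explanations. The choice of normalization or background as its whole cause is argued against, for the settings run. The smallest shift toward heart over both sets and all these settings was 0.049 (log2). All settings start from the same intensities, so a technical difference between the arrays of a pair would pass this check too and is not covered by it. A smaller share of cells like the MEF array in the miR-133 sort is argued against too as the whole cause of the heart-high shift. The 20.6% of MEF signal it would need gives a MEF-high difference of 0.66, while 0.14 was observed (bootstrap interval 0.12 to 0.18). Fibroblasts given the factors but not converted may have another profile than MEF, so a differing share of them stays open. The 6 arrays make 10 splits, too few for a share under 0.05. With day as a block, the 6 splits that part only 1 pair repeat the real arm difference of that day, so they are no comparison with chance. Counting the real one, 5 splits were as large as it for heart-high probes (highest other 0.162) and 5 for MEF-high probes (highest other 0.248), and all the others among these part only 1 pair. Among the 4 that part every pair, the real values were 0.141 and 0.200 and the highest others 0.0672 and 0.119. These values are the set's mean coefficient minus that of probes in neither set, without sign, which is another measure than the median shift. All 10 splits gave 0 calls, the real one included, so the calls tell nothing here. A response to miR-133 and differences of another kind between sorts or between arrays stay open.

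The lower heart-high probes on the Snai1 array could be spread between arrays of one label. Against the first day 7 array their median was −0.051 in place of −0.28, and the 2 same-label arrays differed by 0.18, values that this explanation needs. Both values hold for the scanner files as assigned. By the days of the authors' value table, the first array would be of another day. More cells like the MEF array in the GFP sort of the Snai1 sample, as the whole cause, are argued against. The 41.5% of MEF signal needed for the fall gives a MEF-high rise of 1.24, while 0.16 was observed (bootstrap interval 0.067 to 0.24). Unconverted fibroblasts that had been given the factors are not covered by these values. An effect of Snai1 stays open. That the second day 7 array holds GMT alone, as its description has it, was not settled. Its difference from the first had the miR-133 sign at 16 of the 18 probes and at 10 of the 13 chosen without these 2 arrays. GMT alone would give the opposite sign and a like array no set sign. Session and array differ as well, and by the days of the authors' value table so would the day.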
